A study of Homo sapiens with 12 samples.

How the data were processed

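Gene expression was measured on 12 Affymetrix Human Gene 2.0 ST arrays, 1 per RNA sample, from the colorectal cancer cell lines HCT116, SW48 and RKO, each labelled as wild type for p53. Per the labels' protocols, cells were left untreated or were given 10 µM Nutlin-3a, a small molecule that blocks binding of MDM2 to p53 and so stabilizes p53, for 8 h. This makes 6 groups of 2 arrays. The labels describe duplicates without saying whether they were separate cultures, so p-values measure the spread between these samples only, which may be technical. The labels also carry details that do not settle how the samples were made: the extraction text speaks of thyroids, the growth text names HCT116 only, and the dye field and the labelling text name different labels. Thyroid marker genes were therefore included among the cell type markers that were checked.

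The values used were the deposited log2 expression values, 1 per probe set and array, from the authors' value table. Per the submitters' processing notes, the Affymetrix GCOS software was used; its version, the background correction, the summarization of probes and the normalization between arrays are not given in the sources used here. The log base is not stated either. Base 2 was taken from the range of the values, from 2.22 to 13.45, which is that of log2 array signals. The column medians lay between 4.98 and 5.05, so the arrays had been brought to 1 scale before deposit, and the direction is that of signal on each array. No 2 columns were identical. All columns of the table were matched to samples, and columns of samples not used numbered 0.

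The table held 37270 probe sets. A table of the platform's annotation gave a single gene symbol to 14530 of them (39.0%), several symbols to 0 and none to 22740, which were not used in the tests of genes. Gene numbers of all 14530 were found in the NCBI RefSeq gene table of assembly GRCh38.p14, which changed 0 symbols and supplied gene types and neighbouring genes. No genome build is given for the probe sets, so no coordinates are reported. Where a symbol had more than 1 probe set (395 genes), the one with the highest mean over all 12 arrays was used. This gave 14118 genes, of which 11730 were protein-coding, 2006 noncoding (1359 long noncoding and 611 microRNA genes) and 382 pseudogenes. No filter on dim signal was applied. A microRNA gene's probe set covers the locus of its precursor and can also read a host transcript.

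Models were fitted with limma 3.58.1 in R 4.3.3. All 12 arrays entered 1 linear model of 6 group means with empirical Bayes moderation (6 residual and 3.71 prior degrees of freedom). The contrasts were Nutlin-3a minus untreated in each line, their mean over the 3 lines, an F test with 2 degrees of freedom that the 3 effects are equal, and an F test that the 3 untreated means are equal. P-values were adjusted over genes by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Log2 fold changes are given ± their standard error from this model, with n = 2 arrays per group, and levels as mean ± SD over the 2 arrays. The number of arrays limits the precision. No batch, scan date or slide was used, and cell line cannot be told apart from any culture or array batch that follows it.

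A set of 24 gene lists was fixed before the data were examined: 6 lists of p53 target genes by function, p53-linked noncoding RNAs, DNA replication and E2F genes, G2 and mitosis genes, ribosome biogenesis and MYC genes, integrated stress and unfolded protein genes, cholesterol synthesis genes, interferon-stimulated genes, NF-kB and inflammatory genes, immediate early genes, mismatch repair genes, intestinal epithelial identity genes, mesenchymal genes, genes named with the study, markers of thyroid, immune, fibroblast and endothelial cells, and housekeeping genes. Of the p53 target lists, the genes with a named probe set were 16 of 21 for metabolism and autophagy and 10 of 19 for apoptosis. They were 10 of 16 for secreted and membrane proteins and 5 of 10 for feedback regulators. They were 4 of 12 for cell cycle arrest and 4 of 11 for DNA repair. Counts of list members below are of measured genes only. Each list was tested in each line with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists of a line. Of the 72 such tests 34 passed. All 72 were also run with a correlation estimated from the data, and 29 passed. Tests of the differences between lines for each list were added after the data had been seen.

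Genes were named by a rule fixed before the data were examined. In each line these are the 8 largest rises and the 8 largest falls among called genes whose Nutlin-3a arrays both lay on the same side of both untreated arrays, up to 3 members of each list with the largest change, and 8 genes chosen in advance, of which MATR3, RRM2B and GPX1 had a named probe set and the others are not analysed here. For the mean effect and for genes shared by the 3 lines these are the 8 largest rises and falls, for noncoding genes all that met the criterion, for differences between lines the 12 with the widest range, and for untreated cells the 5 in each line that most exceeded the mean of the other 2 lines, and members of 4 kinds of list. Genes named outside the rule are said to be so.

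The fits were tested on simulated data built from the untreated means and the moderated variances of these 14118 genes. Of 100 genes changed by 0.5 on the log2 scale, the tests in single lines recovered 77% in HCT116, 78% in SW48 and 76% in RKO, and 99%, 100% and 97% of those changed by 1. The mean over lines recovered 100% at both sizes, and the test for differences between lines recovered 42% and 90%. False calls made up 6.38%, 5.24% and 3.35% of calls in the 3 lines, 4.55% for the mean and 7.04% for differences. Of 100 unchanged lists, 0% had a p under 0.05. Of 20 lists raised by 0.3, 100% did. The simulated noise was independent between genes, so these lists do not test the preset correlation for genes that vary together. Each result was computed again with quantile normalization, centring of array medians, a filter that kept the 10632 genes above the median probe set in some group, an intensity trend with a robust prior, each line fitted alone, all probe sets tested, the mean over a gene's probe sets, stricter thresholds, the replicate number as a block, and each array left out in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.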

Results

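Expression profiles were collected from 3 human colorectal cancer cell lines with wild-type p53, HCT116, SW48 and RKO, each untreated or exposed to 10 µM Nutlin-3a for 8 h, with 2 arrays in each of the 6 groups. Nutlin-3a releases p53 from its inhibitor MDM2, and the series concerns the targets of p53 in these cells, among them long noncoding RNAs. Over all probe sets, the 2 arrays of a group correlated at r between 0.996 and 0.997, treated and untreated arrays of a line at 0.995 to 0.996, and arrays of different lines at 0.957 to 0.965. The median absolute difference between the arrays of a group was 0.090 to 0.101 on the log2 scale. With 2 arrays per group, both measures are the same for the 2 arrays, so they cannot single out a deviating array.

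In HCT116 cells, Nutlin-3a raised known p53 target genes and lowered genes of DNA replication. TP53INP1, whose product acts in the p53 stress response and in autophagy, rose 5.58-fold (log2 fold change 2.48 ± 0.077, adjusted p = 4.75e-07). TP53I3, an oxidoreductase linked to p53-dependent apoptosis, rose 4.59-fold (standard error 0.094 on the log2 scale, adjusted p = 2.55e-06), and SESN1, a stress-induced inhibitor of mTORC1 signalling, rose 3.69-fold (log2 fold change 1.88 ± 0.070, adjusted p = 1.35e-06). The ceramidase gene ACER2 (1.83 ± 0.073), the sulfatase gene SULF2 (1.81 ± 0.20), the dynein gene DNAI3 (2.07 ± 0.12) and SUSD6 (1.67 ± 0.086) rose as well. The largest rise was that of the probe set of the microRNA gene MIR3189 (2.66 ± 0.12), which lies inside GDF15 and may not be read apart from it; GDF15, a secreted stress cytokine of the TGF-beta family, rose 2.92-fold (log2 fold change 1.54 ± 0.096, adjusted p = 2e-05).

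Among the lists of p53 targets in HCT116, 10 of 16 metabolism and autophagy genes, 7 of 10 apoptosis genes, 6 of 10 secreted and membrane proteins, 4 of 5 feedback regulators, 3 of 4 cell cycle arrest genes and 3 of 4 DNA repair genes rose, and 0 fell. Adjusted over the list alone, these counts were 11, 7, 7, 5, 3 and 4. The list tests gave adjusted p-values from 6.16e-20 for metabolism and autophagy to 1.13e-07 for cell cycle arrest, and at most 0.0228 with an estimated correlation. BBC3, which encodes the pro-apoptotic BH3 protein PUMA, rose by 1.33 ± 0.098, the apoptosome gene APAF1 by 1.19 ± 0.069, the polo-like kinase genes PLK3 and PLK2 by 1.44 ± 0.10 and 1.27 ± 0.093, and RPS27L by 1.13 ± 0.069. RRM2B, the p53-inducible ribonucleotide reductase subunit, rose 2.13-fold (log2 fold change 1.09 ± 0.083, adjusted p = 6.55e-05). GPX1, a glutathione peroxidase, rose by 0.52 ± 0.073, and MATR3, which encodes the nuclear matrix protein Matrin 3, changed by 0.068 ± 0.053 without passing the test (adjusted p = 0.546). These 3 are the measured members of the list of genes named with the study, which was drawn up from the study itself and is not independent evidence of a direction; 2 of the 3 rose, also when adjusted over the list alone (adjusted p = 0.000166 for the list). Of the 7 measured p53-linked noncoding RNAs, PURPL (1.53 ± 0.14) and MIR22HG (0.62 ± 0.089) rose (2 adjusted over the list alone; list adjusted p = 0.004). Of 9 integrated stress and unfolded protein genes, 4 rose (7 adjusted over the list alone; list adjusted p = 1.13e-07), among them DDIT3, the transcription factor CHOP (0.92 ± 0.11), and the asparagine synthetase gene ASNS (0.61 ± 0.057).

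Of 28 DNA replication and E2F genes measured in HCT116, 20 fell and 0 rose, with a median log2 fold change of -0.36 (list adjusted p = 7.51e-21; 0.00496 with an estimated correlation). Adjusted over the list alone, 22 fell and 1 rose. The cyclin E genes CCNE1 and CCNE2 changed by -0.90 ± 0.056 and -0.82 ± 0.079, and E2F2 by -0.70 ± 0.072. Of 26 G2 and mitosis genes 6 fell and 0 rose (13 fell adjusted over the list alone; list adjusted p = 3.46e-08), led by the phosphatase gene CDC25A (-0.83 ± 0.074). The largest falls outside the lists were FHDC1 (-1.21 ± 0.17), the transcription factor genes MYB (-1.03 ± 0.091), ZNF367 (-1.03 ± 0.061) and DLX1 (-0.89 ± 0.081), the antisense RNA ST3GAL6-AS1 (-0.91 ± 0.11), TTPA (-0.91 ± 0.11) and LRRC26 (-0.90 ± 0.063). The other 13 lists did not pass in HCT116 (adjusted p from 0.0832 to 0.892). The lowest, mismatch repair, passed with quantile normalization (list adjusted p = 0.049) and with all probe sets tested (0.044). Single members that passed were MSH6 of the 6 mismatch repair genes (-0.76 ± 0.061), the immediate early gene EGR1 of 16 (0.84 ± 0.064), and the interferon-stimulated genes TLR3 (1.36 ± 0.068) and IFIH1 (0.35 ± 0.086) of 14. Further ones were PTGS2 of 7 inflammatory genes (0.58 ± 0.12), STARD4 (0.36 ± 0.065) and SQLE (-0.35 ± 0.062) of 10 cholesterol synthesis genes, VIM of 8 mesenchymal genes (-0.46 ± 0.083) and the fibroblast marker THY1 of 3 (-0.32 ± 0.070). THY1 lost its call without any 1 HCT116 array (adjusted p up to 0.138), STARD4 (0.101), SQLE (0.101), PTGS2 (0.125) and VIM (0.111) without 3 of those 4, each in turn, and IFIH1 without 9 of the 12 arrays (0.281). No member passed among 11 ribosome biogenesis and MYC genes, 14 intestinal identity genes, 7 thyroid, 5 immune and 5 endothelial markers and 6 housekeeping genes.

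Across HCT116, 721 of 14118 genes were called, 435 higher and 286 lower, of which 32 rose and 3 fell at least 2-fold. The higher genes made up 60.3% of calls, and 72.3% when each array was centred on its median. Without any 1 of the 4 HCT116 arrays the count fell to between 260 and 341.

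In SW48 cells the strongest rise was that of GDF15, 6.04-fold (log2 fold change 2.59 ± 0.096, adjusted p = 2.44e-06). TP53INP1 (1.73 ± 0.077), SESN1 (1.69 ± 0.070), SESN2 (1.54 ± 0.078) and SULF2 (1.79 ± 0.20) rose too, as did SPATA18, a p53 target of mitochondrial quality control (1.67 ± 0.10), and UNC5B-AS1, an antisense RNA that overlaps UNC5B (1.64 ± 0.22). The probe set of MIR34A, a microRNA gene activated by p53, rose 2.73-fold (log2 fold change 1.45 ± 0.079, adjusted p = 1.97e-05). It lies within the host gene MIR34AHG.

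Of the p53 target lists in SW48, 10 of 16 metabolism and autophagy genes rose, with 6 of 10 apoptosis genes, 5 of 10 secreted and membrane proteins, 3 of 5 feedback regulators, 2 of 4 cell cycle arrest genes and 3 of 4 DNA repair genes, and 0 fell. The counts adjusted over the list alone were 11, 6, 6, 4, 3 and 4, and the list adjusted p-values lay between 7.31e-23 and 1.21e-05, and at most at 0.0367 with an estimated correlation. BAX (1.12 ± 0.072) and PIDD1 (1.01 ± 0.097), genes of the mitochondrial and PIDDosome routes of apoptosis, TP53I3 (1.10 ± 0.094), PLK3 (1.21 ± 0.10), TRIAP1 (1.23 ± 0.083) and RRM2B (1.14 ± 0.083) were among them. Of 7 p53-linked noncoding RNAs 3 rose, MIR34A, PURPL (1.33 ± 0.14) and LINC00475 (0.37 ± 0.075), 5 adjusted over the list alone (list adjusted p = 1.73e-08). GPX1 rose by 0.34 ± 0.073 and MATR3 stood at -0.045 ± 0.053 (adjusted p = 0.75); 2 of the 3 genes named with the study rose, also adjusted over the list alone (list adjusted p = 0.00214, and 0.0367 with an estimated correlation). GPX1 lost its call without 10 of the 12 arrays, each in turn (adjusted p up to 0.188), and LINC00475 without 3 of the 4 SW48 arrays (0.157).

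Of 28 DNA replication and E2F genes measured in SW48, 22 fell and 0 rose, with a median of -0.63 (list adjusted p = 1.17e-36; 0.00116 with an estimated correlation), and adjusted over the list alone 26 fell and 1 rose. The replication factor gene MCM10 (-0.97 ± 0.060), CCNE2 (-0.94 ± 0.079), the ubiquitin ligase genes UHRF1 (-0.94 ± 0.065) and DTL (-0.91 ± 0.058), E2F1 (-0.87 ± 0.083) and the origin licensing gene CDC6 (-0.85 ± 0.066) were the largest falls with ZNF367 (-1.08 ± 0.061) and MSH6 (-0.89 ± 0.061). Of 26 G2 and mitosis genes 6 fell (17 adjusted over the list alone; list adjusted p = 1.66e-11), with CDC25A at -0.60 ± 0.074. Of 6 mismatch repair genes MSH6 fell and 5 did not pass; the list had an adjusted p of 0.00491, and an adjusted p = 0.171 with an estimated correlation. Of 9 integrated stress genes DDIT3 rose (0.79 ± 0.11; list adjusted p = 0.0162, and adjusted p = 0.107 with an estimated correlation), and adjusted over the list alone 2 rose and 2 fell. The other 12 lists did not pass (adjusted p from 0.44 to 0.947). The Wnt-linked stem cell gene LGR5 fell among 14 intestinal identity genes (-0.63 ± 0.093; adjusted p = 0.0559 without Nutlin-3a replicate 2), FOSL1 rose among 16 immediate early genes (0.42 ± 0.075) and STARD4 among 10 cholesterol synthesis genes (0.33 ± 0.065). FOSL1 lost its call without untreated replicate 1 or Nutlin-3a replicate 2 (adjusted p up to 0.121) and STARD4 without 3 of the 4 SW48 arrays (0.167). No other member of those 12 lists passed.

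In SW48, 441 genes were called, 195 higher and 246 lower, with 28 rises and 1 fall of at least 2-fold. Higher genes made up 44.2% of calls, 50.8% with quantile normalization, 55.2% with all probe sets tested, 55.3% at an adjusted p under 0.01 and 65.2% with SW48 fitted alone, so the more frequent direction depended on these choices. Leaving out any 1 of the 4 SW48 arrays gave between 188 and 251.

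In RKO cells, TP53INP1 rose 3.72-fold (log2 fold change 1.90 ± 0.077, adjusted p = 5.42e-06) and the long noncoding RNA PURPL, a p53-induced transcript, rose 3.46-fold (log2 fold change 1.79 ± 0.14, adjusted p = 0.000139). ACER2 (1.71 ± 0.073), DNAI3 (1.69 ± 0.12), SESN1 (1.44 ± 0.070), BBC3 (1.42 ± 0.098) and the epithelial transcription factor gene GRHL3 (1.70 ± 0.13) rose, and the MIR3189 probe set rose by 2.60 ± 0.12. BMP4 (-0.70 ± 0.089) and FGF9 (-0.60 ± 0.087), which encode secreted growth factors, and MYB (-0.67 ± 0.091) fell. FGF9 lost its call without untreated replicate 1 or Nutlin-3a replicate 2 (adjusted p up to 0.0716), and MYB without untreated replicate 2 or Nutlin-3a replicate 2 (0.052).

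Of the p53 target lists in RKO, 8 of 16 metabolism and autophagy genes, 7 of 10 apoptosis genes, 5 of 10 secreted and membrane proteins, 3 of 5 feedback regulators, 4 of 4 DNA repair genes and 1 of 4 cell cycle arrest genes rose, and 0 fell. Adjusted over the list alone the counts were 9, 7, 7, 4, 4 and 2. The tests of the first 5 had adjusted p-values between 5.61e-17 and 1.78e-08, and at most 0.013 with an estimated correlation; cell cycle arrest had 0.0107, and an adjusted p = 0.0741 with an estimated correlation. TP53I3 (1.38 ± 0.094), PIDD1 (1.14 ± 0.097), the cytokine gene LIF (1.01 ± 0.074), KITLG, which encodes the KIT ligand (0.87 ± 0.081), and RRM2B (0.96 ± 0.083) rose, whereas PLK2 stood at 0.062 ± 0.093 (adjusted p = 0.798). Of 7 noncoding RNAs PURPL rose (2 adjusted over the list alone; list adjusted p = 0.00292, and 0.0442 with an estimated correlation). GPX1 (0.22 ± 0.073, adjusted p = 0.168) and MATR3 (-0.058 ± 0.053, adjusted p = 0.651) did not pass. The list of genes named with the study, with RRM2B called and 2 called adjusted over the list alone, had an adjusted p of 0.0167, and an adjusted p = 0.086 with an estimated correlation.

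Of 28 replication and E2F genes in RKO 7 fell and 0 rose, with a median of -0.20 (list adjusted p = 1.43e-10; 0.013 with an estimated correlation), and 20 fell and 2 rose adjusted over the list alone. CCNE1 (-0.47 ± 0.056) fell furthest. Of 11 ribosome biogenesis and MYC genes, NOP16 (-0.39 ± 0.074), MYC (-0.36 ± 0.065) and NOLC1 (-0.31 ± 0.065) fell (5 adjusted over the list alone). The list had an adjusted p of 6.92e-06, and 0.0241 with an estimated correlation. NOP16 (adjusted p up to 0.141) and MYC (0.149) lost the call without any 1 of the 4 RKO arrays, and NOLC1 without any 1 of the 12 arrays (0.235). MSH6 (-0.45 ± 0.061; adjusted p = 0.0523 without Nutlin-3a replicate 2) was the called gene of 6 in mismatch repair (list adjusted p = 0.00437, and adjusted p = 0.171 with an estimated correlation). The largest falls were MIRLET7F1 (-1.15 ± 0.16), a let-7 microRNA gene inside MIRLET7A1HG, and KRCC1 (-0.98 ± 0.13), with LONRF1 (-0.74 ± 0.11), UTS2 (-0.63 ± 0.12) and KRTAP2-3 (-0.59 ± 0.091). Without untreated replicate 1 or Nutlin-3a replicate 2 the calls of MIRLET7F1 (adjusted p up to 0.0552), LONRF1 (0.0844), UTS2 (0.168) and KRTAP2-3 (0.0845) were lost, those of the last 2 also without other arrays. The other 13 lists did not pass (adjusted p from 0.105 to 0.99), G2 and mitosis among them with CDC25A called of 26 (-0.38 ± 0.074). With an intensity trend and a robust prior the G2 and mitosis list passed (list adjusted p = 0.0188). The called members of the rest were DDIT3 of 9 integrated stress genes (0.56 ± 0.11), STARD4 of 10 cholesterol genes (0.43 ± 0.065), TLR3 of 14 interferon-stimulated genes (0.45 ± 0.068), DUSP6 of 16 immediate early genes (0.34 ± 0.062) and the Wnt target AXIN2 of 14 intestinal genes (-0.50 ± 0.067). CDC25A lost its call without 10 of the 12 arrays (adjusted p up to 0.173), DDIT3 without 9 (0.168), DUSP6 without 6 (0.133), STARD4 without any RKO array (0.074) and TLR3 without untreated replicate 2 or Nutlin-3a replicate 2 (0.0833).

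In RKO 285 genes were called, 173 higher and 112 lower, with 22 rises and 1 fall of at least 2-fold. Higher genes made up 60.7% of calls, 40.9% with an intensity trend and a robust prior, 83.3% at an adjusted p under 0.01 and 100% with RKO fitted alone. Without Nutlin-3a replicate 2 the share was 83.5%. Leaving out any 1 of the 4 RKO arrays gave between 97 and 120, and either untreated HCT116 array 163.

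**Figure D1:**
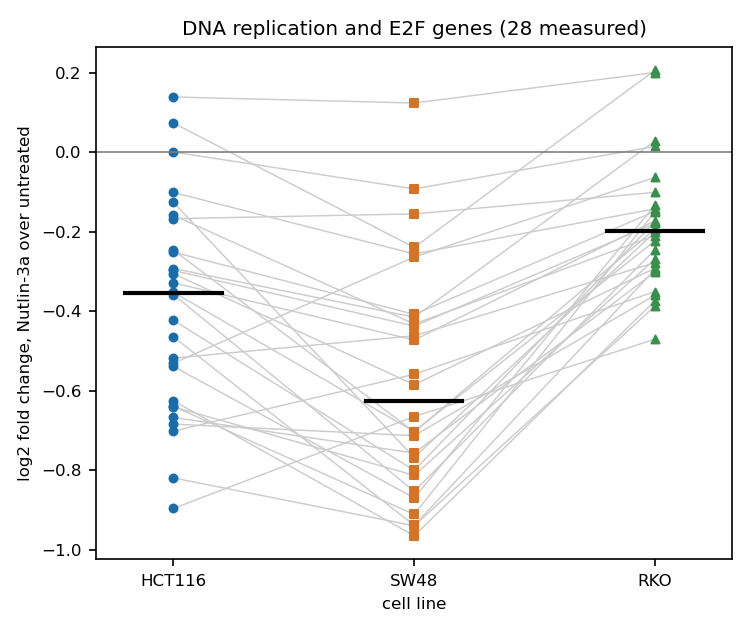
Log2 fold change, Nutlin-3a over untreated, of the 28 measured DNA replication and E2F genes in each cell line; each point is a gene, grey lines join a gene across lines and black bars are medians. The medians are -0.36 in HCT116, -0.63 in SW48 and -0.20 in RKO.

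Averaged over the 3 lines, the stress and p53 target genes TP53INP1 (2.03 ± 0.044), GDF15 (1.82 ± 0.055), SESN1 (1.67 ± 0.041), DNAI3 (1.62 ± 0.070), TP53I3 (1.56 ± 0.054), PURPL (1.55 ± 0.079) and ACER2 (1.53 ± 0.042) rose most, with the MIR3189 probe set (2.38 ± 0.071). The largest falls were ZNF367 (-0.81 ± 0.035), CCNE2 (-0.72 ± 0.046), CCNE1 (-0.68 ± 0.032), MCM10 (-0.65 ± 0.035) and CDC25A (-0.61 ± 0.043), with MYB (-0.74 ± 0.052), the mismatch repair gene MSH6 (-0.70 ± 0.035) and FHDC1 (-0.81 ± 0.10). In all, 1520 genes were called for the mean effect, 611 higher and 909 lower, and of these 20 rose and 0 fell by at least 2-fold on average. The falls were thus more numerous than the rises, while only rises reached 2-fold on average.

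Which p53 responses the lines hold in common was asked by counting genes called in the same direction in each. There were 77 such genes higher and 24 lower, against 0.0736 and 0.0395 that independent lists of these sizes would share. Each line had its own untreated arrays. The 3 contrasts share 1 variance estimate per gene, however, so the lists are not independent even without a shared response. Over pairs of lines 4 genes were called in opposite directions. Of the 77 genes, 14 rose at least 2-fold in every line: TP53INP1, GDF15, SESN1, SESN2, DNAI3, TP53I3, ACER2, SUSD6, the mTORC1 inhibitor gene DDIT4, TIGAR, a regulator of glycolysis, EFNB1, IKBIP, MIR3189 and PURPL, of which EFNB1 and IKBIP were named after their values were seen. The shared falls included JPH1 (-0.76 ± 0.089 in HCT116, -0.51 ± 0.089 in SW48 and -0.50 ± 0.089 in RKO) besides the cell cycle genes above. In RKO, CCNE2 (adjusted p up to 0.195) and CDC25A (0.173) each lost the call without 10 of the 12 arrays, and ZNF367 (0.126), MCM10 (0.0965) and JPH1 (0.149) without any 1 RKO array. MYB lost its RKO call without untreated replicate 2 or Nutlin-3a replicate 2 (0.052). In SW48, JPH1 lost the call without untreated replicate 1 or Nutlin-3a replicate 1 (0.108), and MYB without 3 of the 4 SW48 arrays (0.0961). Without any 1 array the shared genes numbered 50 to 72, with 47 to 60 higher and 3 to 13 lower. An adjusted p under 0.01 left 40 higher and 2 lower, and each line fitted alone 24 higher and 0 lower, whereas an intensity trend with a robust prior gave 127 and 88. Across all 14118 genes, which are not independent replicates, the fold changes of line pairs correlated at Pearson r of 0.354 to 0.367 (Spearman 0.167 to 0.261), and over genes called in either line at 0.641 to 0.7 (Spearman 0.59 to 0.671).

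**Figure D2:**
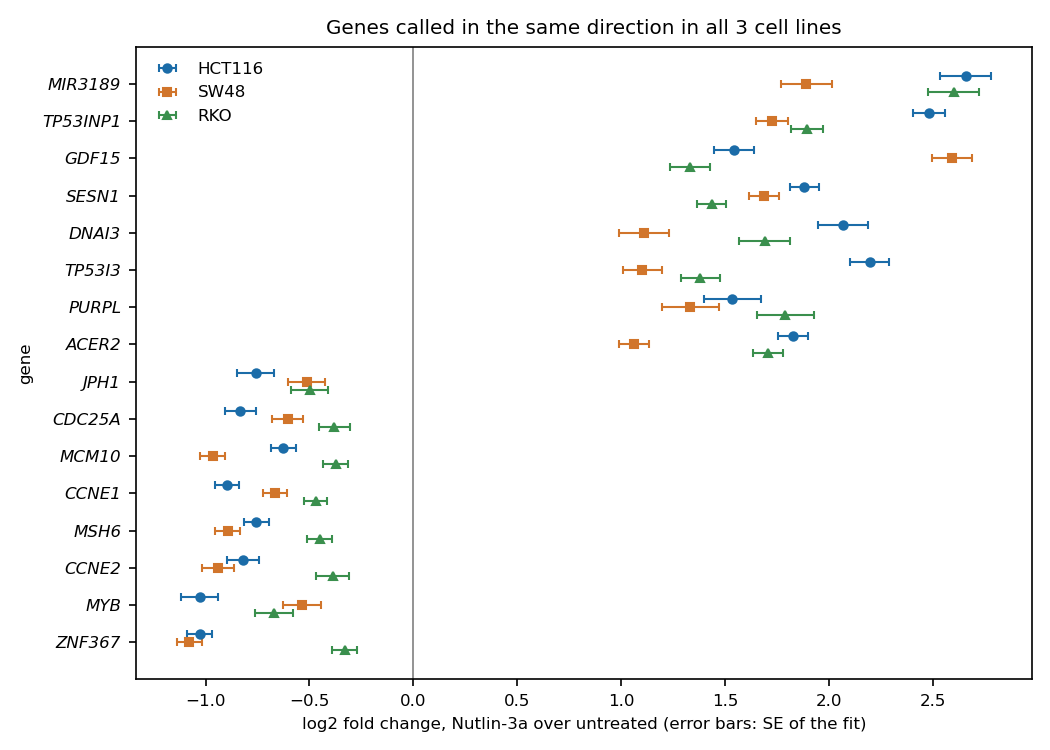
Log2 fold change with its standard error (horizontal axis) of the 8 largest shared rises and 8 largest shared falls (vertical axis) in HCT116, SW48 and RKO, 2 arrays per group. TP53INP1 rises by 2.48, 1.73 and 1.90, and ZNF367 stands at -1.03, -1.08 and -0.33.

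Among 2006 noncoding genes tested, 2 rose at least 2-fold in every line, PURPL and MIR3189. The MIR3189 probe set lies inside GDF15, which rose as well, and may not be read apart from it. PURPL rose 2.90-fold (log2 fold change 1.53 ± 0.14, adjusted p = 0.000218) in HCT116 and by 1.33 ± 0.14 in SW48. Its untreated levels were 5.63 ± 0.0071 in HCT116, 5.00 ± 0.071 in SW48 and 7.03 ± 0.036 in RKO. One more, NRAV, a long noncoding RNA first described in antiviral responses, rose in the 3 lines by 0.45 ± 0.064, 0.38 ± 0.064 and 0.31 ± 0.064, below the 2-fold mark, and was named after its values were seen. Noncoding genes called higher numbered 24 in HCT116, 12 in SW48 and 7 in RKO, and those called lower 12, 9 and 4. The other long noncoding RNAs of the array with no symbol here are not analysed here.

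Whether the response differed between lines was tested for each gene. SULF2 rose in HCT116 and SW48 (1.81 ± 0.20 and 1.79 ± 0.20) and stood at -0.46 ± 0.20 in RKO (adjusted p = 0.0103 for the difference). MIR34A, SPATA18 and RPTN, a gene of the cornified envelope, were called in SW48 (1.45 ± 0.079, 1.67 ± 0.10 and 1.51 ± 0.13). They were not called in HCT116 (0.14 ± 0.079, 0.38 ± 0.10 and 0.0055 ± 0.13) or RKO (0.19 ± 0.079, 0.072 ± 0.10 and 0.017 ± 0.13). The adjusted p-values of the differences were 0.0041, 0.00629 and 0.0115. The double-stranded RNA receptor gene TLR3 rose by 1.36 ± 0.068 in HCT116 and 0.45 ± 0.068 in RKO and stood at 0.11 ± 0.068 in SW48 (difference adjusted p = 0.0041). PTAFR, STAT4 and PLK2 had their largest values in HCT116 (1.58 ± 0.15, 1.36 ± 0.11 and 1.27 ± 0.093), against 0.038 ± 0.15, -0.13 ± 0.11 and 0.58 ± 0.093 in SW48 and 0.031 ± 0.15, 0.17 ± 0.11 and 0.062 ± 0.093 in RKO (differences adjusted p = 0.0239, 0.00906 and 0.012).

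LACC1, an enzyme gene of macrophage metabolism, and GRHL3 rose in HCT116 (1.54 ± 0.12 and 1.10 ± 0.13) and RKO (1.03 ± 0.12 and 1.70 ± 0.13) and stood at -0.21 ± 0.12 and 0.15 ± 0.13 in SW48 (differences adjusted p = 0.0083 and 0.0218). GDF15 rose in all 3 lines and most in SW48 (difference adjusted p = 0.00906). Its untreated level there was 9.29 ± 0.22, against 11.32 ± 0.10 in HCT116 and 11.27 ± 0.022 in RKO. The 99th percentile of all values was 11.42, close to the levels in those 2 lines. The test of the array ceiling below took only genes without a called rise in some line, so it did not cover GDF15. The MIR3189 probe set inside it ordered the lines otherwise, with 2.66 ± 0.12 in HCT116, 1.89 ± 0.12 in SW48 and 2.60 ± 0.12 in RKO (difference adjusted p = 0.132). MIRLET7F1 fell in RKO alone among the calls, from an untreated level of 4.58 ± 0.21 (difference adjusted p = 0.04). Altogether 71 of 14118 genes differed between lines. That count fell to between 15 and 39 without any 1 array, and LACC1, SPATA18, MIR34A, GDF15 and TLR3 were the ones of these 12 genes whose difference passed in every omission.

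**Figure D3:**
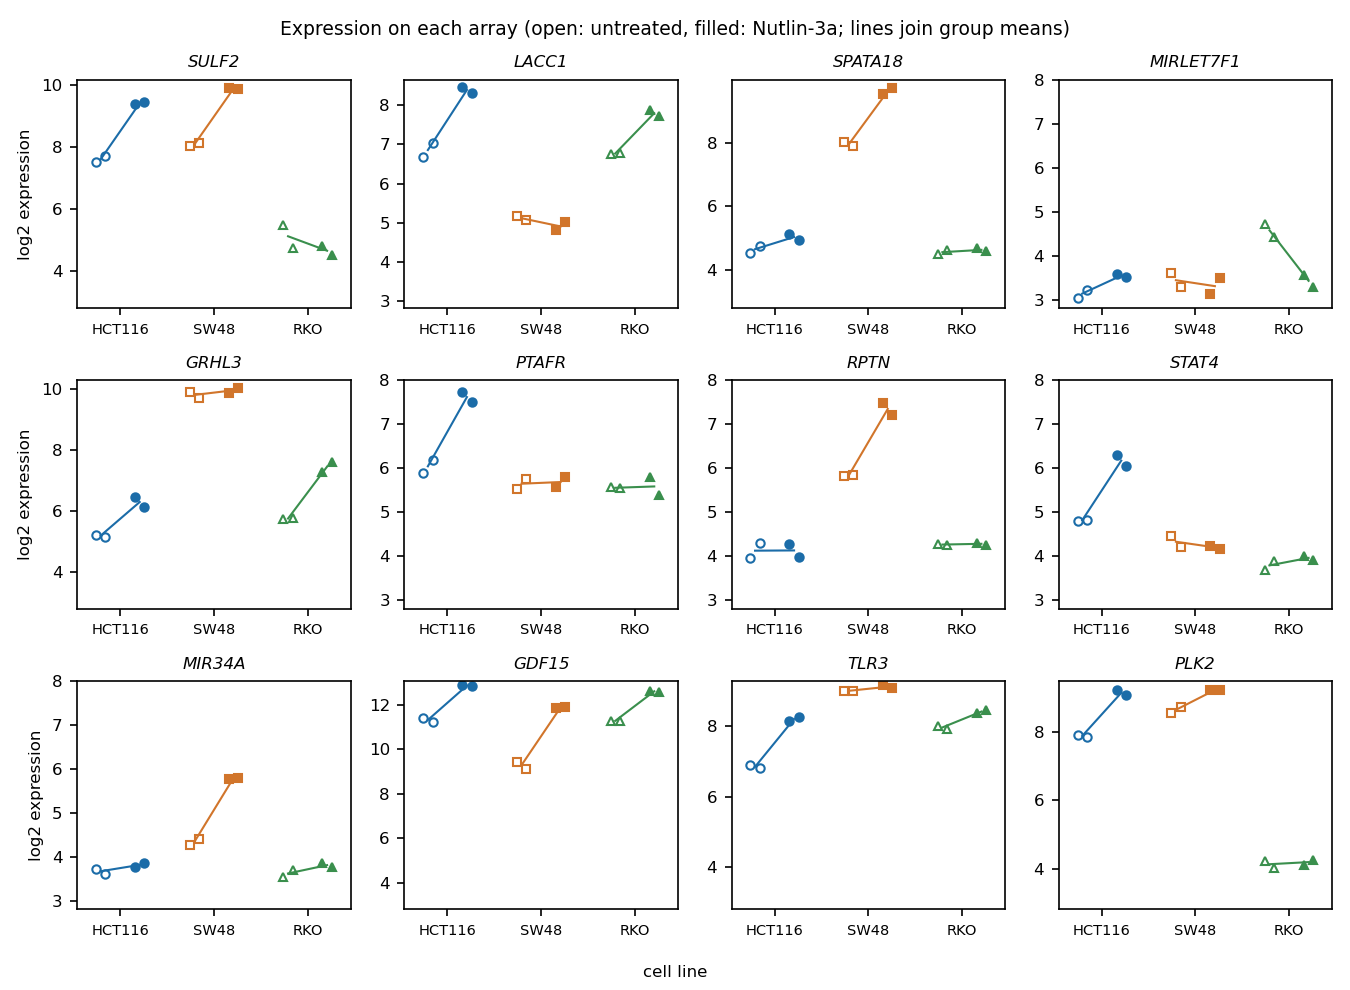
Log2 expression (vertical axis) on each array of the 12 genes with the widest range of effects, by cell line (horizontal axis); open symbols are untreated, filled symbols Nutlin-3a, and lines join the group means of 2 arrays. MIR34A moves from 4.34 to 5.79 in SW48 and lies below 4 on all arrays of the other lines.

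The untreated lines differed in 8197 of 14118 genes (58.1%). HCT116 cells had the highest levels of LAPTM4B, a lysosomal membrane protein gene (12.17 ± 0.017, against 3.92 ± 0.053 in SW48 and 3.62 ± 0.041 in RKO). They also led in the DNA translocase gene HLTF (9.97 ± 0.048, 3.58 ± 0.062 and 3.76 ± 0.028), the Wnt antagonist gene DKK1 (10.21 ± 0.0079, 3.76 ± 0.19 and 4.36 ± 0.085), MSN and GTSF1. SW48 cells had the highest levels of the fatty acid receptor gene CD36 (11.04 ± 0.073, against 3.31 ± 0.049 in HCT116 and 3.20 ± 0.024 in RKO), GPR15 and the noncoding RNAs MIR31HG, MYO16-AS1 and LINC03033. RKO cells had the highest levels of BST2, the antiviral protein tetherin (11.23 ± 0.033, against 4.66 ± 0.17 in HCT116 and 4.30 ± 0.23 in SW48), the DNA sensor gene CGAS (8.88 ± 0.037, 3.77 ± 0.15 and 4.01 ± 0.23), DCLK1, PDE7B and GRPR.

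Most of the 14 measured intestinal epithelial identity genes differed between the untreated lines, as did 58.1% of all genes, and others, such as CDX1 (adjusted p = 0.494), did not. EPCAM, an epithelial adhesion gene, stood at 6.03 ± 0.56 in RKO against 11.02 ± 0.036 in HCT116 and 11.12 ± 0.013 in SW48 (adjusted p = 9.66e-09), and the epithelial splicing regulator gene ESRP1 at 4.28 ± 0.0038 against 10.55 ± 0.018 and 10.71 ± 0.060. The intestinal transcription factor gene CDX2 (9.60 ± 0.040, against 7.38 ± 0.054 in HCT116 and 7.52 ± 0.024 in RKO) and CEACAM5 (9.25 ± 0.12, 4.37 ± 0.26 and 4.67 ± 0.0072) were highest in SW48. The same held for LGR5 (6.75 ± 0.037, 3.84 ± 0.13 and 3.72 ± 0.18) and AXIN2 (11.75 ± 0.067, 8.50 ± 0.095 and 9.52 ± 0.058). The mesenchymal genes AXL (11.20 ± 0.056, 9.90 ± 0.067 in HCT116 and 6.31 ± 0.15 in SW48) and SNAI2 (7.94 ± 0.037, 6.35 ± 0.15 and 5.16 ± 0.25) were highest in RKO. Of the mismatch repair genes, MSH3 was highest in SW48 (9.85 ± 0.093, against 7.79 ± 0.060 in HCT116 and 7.63 ± 0.10 in RKO). Among p53 targets, PLK2 was low in RKO (4.13 ± 0.14, against 7.89 ± 0.023 and 8.66 ± 0.14), as was KITLG (6.88 ± 0.14, 11.79 ± 0.049 and 10.64 ± 0.0048), and SPATA18 was high in SW48 (7.95 ± 0.094, 4.66 ± 0.16 and 4.56 ± 0.079). Line cannot be told apart from any culture or array batch that follows it.

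Levels of markers of other cell types varied, against 5.04 for the median probe set. The 7 thyroid markers had a median level of 4.97 and a highest of 6.03 (NKX2-1), the 5 immune markers 4.74 and 9.28 (CD68, a lysosomal protein gene that many cell lines express), the 3 fibroblast markers 3.58 and 5.66 (THY1), and the 5 endothelial markers 4.94 and 7.03 (ESAM). The list tests of these 4 kinds and of the 6 housekeeping genes did not pass in any line.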

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

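The tests of list differences between lines, the comparison with lists of like brightness, the ratio of summed fold changes and the tests of array floor and ceiling were chosen after the results had been seen; the bound of the brightness comparison was set before its own value was computed, and the regroupings of arrays were not chosen after the results.

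The response to Nutlin-3a differed between lines in 71 genes. Among 100 of the 1350 possible ways to regroup the line-centred arrays into 3 lines within each treatment, 1 gave as many genes, the real one. The highest of the others gave 5. Regrouping mixes arrays of different lines, so real effects of a line add to the spread and lower the other counts. The duplicates may also be technical, so this comparison cannot judge chance differences between cultures. The differences in effect spanned 2.27 on the log2 scale for SULF2, 1.75 for LACC1, 1.59 for SPATA18, 1.56 for MIRLET7F1, 1.55 for GRHL3, 1.55 for PTAFR, 1.51 for RPTN, 1.48 for STAT4, 1.31 for MIR34A, 1.26 for GDF15, 1.24 for TLR3 and 1.20 for PLK2. Leaving out 1 array ended the difference for SULF2 (SW48 untreated replicate 1, adjusted p = 0.0509), STAT4 (HCT116 untreated replicate 1, 0.0547), RPTN (either untreated SW48 array, up to 0.0678), PLK2 (either untreated HCT116 array or HCT116 Nutlin-3a replicate 1, up to 0.068), GRHL3 (any SW48 array and any untreated array of the other lines, up to 0.0844), PTAFR (8 of the 12 arrays, up to 0.0926) and MIRLET7F1 (11 of the 12 arrays, up to 0.12). The untreated levels of MIRLET7F1 lay below the median probe set in all 3 lines. For MIRLET7F1 the exception was SW48 Nutlin-3a replicate 1, and for PTAFR the exceptions were HCT116 untreated replicate 2, SW48 Nutlin-3a replicate 2 and both RKO Nutlin-3a arrays.

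In 43 of these genes, Nutlin-3a gave a called rise in 1 or 2 lines and not in the rest, which makes 67 pairs of a gene and a line without a called rise. A floor of the array would hide a rise in dim genes: 26.9% of the pairs had an untreated level below the median probe set (exact 95% interval 16.8% to 39.1%), so it does not account for most of them and stays open for 18 pairs, among them MIR34A, SPATA18 and RPTN in HCT116 and RKO, STAT4 in SW48 and RKO, and PLK2 in RKO. A ceiling would hide a rise in bright genes, and 2.99% of pairs lay above the 99th percentile of all values (exact 95% interval 0.364% to 10.4%). Few values can exceed that bound by its definition, so a low share was likely and cannot exclude a ceiling. A difference between the cell lines is a hypothesis for these pairs, and it was found and tested on the same arrays. Noise between arrays stays open as well. The cultures may also have differed in ways no label records.

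DNA replication and E2F genes fell less in RKO than in SW48, by a median of 0.399 on the log2 scale (adjusted p = 4.22e-24; 0.0216 with an estimated correlation), with all 28 measured genes on that side. In 10000 random lists of 28 genes matched on mean level, the medians reached 0.0647 at their upper 2.5% bound, which argues against a shift shared by genes of like brightness. On these arrays the p53 targets, summed over their 6 lists, and the replication genes did not weaken alike. The p53 lists differed among themselves. Mean log2 fold changes in SW48 and RKO were 0.524 and 0.257 for the 4 measured cell cycle arrest targets. They were 0.561 and 0.661 for apoptosis targets and 0.484 and 0.575 for secreted and membrane targets. The means of the remaining p53 target lists were somewhat lower in RKO. The summed fold change in RKO over that in SW48 was 0.931 for the 48 measured p53 target genes (bootstrap 95% interval 0.764 to 1.13). For the replication genes it was 0.327 (0.252 to 0.398). The bootstrap resampled genes measured on the same arrays, so these intervals carry no spread between samples. Over 20 alternative settings, all with the preset correlation, the median difference lay between 0.338 and 0.43. A candidate explanation is that replication genes respond later or less in RKO, for example through cell cycle arrest of a different extent, which 1 time point leaves open.

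Other lists differed between lines with the preset correlation and not with an estimated one. The cell cycle arrest list had 4 measured genes of 12, and feedback regulators 5 of 10. SW48 minus HCT116 had medians of -0.36 for p53 cell cycle arrest targets (adjusted p = 0.146 with an estimated correlation), -0.148 for metabolism and autophagy targets (0.195), -0.156 for replication and E2F genes (0.12) and -0.268 for integrated stress genes (0.146). RKO minus HCT116 had -0.13 for p53 feedback regulators (0.195), -0.705 for cell cycle arrest (0.0803), -0.304 for metabolism and autophagy (0.0803), 0.163 for replication and E2F genes (0.0803), 0.134 for G2 and mitosis genes (0.195), -0.115 for ribosome biogenesis and MYC genes (0.234) and -0.287 for integrated stress genes (0.094). RKO minus SW48 had -0.329 for cell cycle arrest (0.195), 0.149 for G2 and mitosis genes (0.182) and -0.157 for ribosome biogenesis and MYC genes (0.12). With the preset correlation too, single omissions of an array ended 4 of these calls: metabolism and autophagy in SW48 minus HCT116 (8 of 12 arrays, adjusted p up to 0.106; -0.0823 and 0.217 with quantile normalization), feedback regulators (4 arrays, up to 0.11, at -0.0792) and ribosome biogenesis (5 arrays, up to 0.0764) in RKO minus HCT116, and cell cycle arrest in RKO minus SW48 (7 arrays, up to 0.148). Quantile normalization also ended those of feedback regulators (0.0746) and ribosome biogenesis (0.0658). Centring (0.0707) and the dim filter (0.0903) ended that of metabolism and autophagy. The dim filter also ended that of cell cycle arrest in RKO minus SW48 (0.0507). Other lists gained a call. With quantile normalization cholesterol synthesis passed in SW48 minus HCT116 (0.16, adjusted p = 0.0127) and RKO minus HCT116 (0.162, 0.0098). With centring fibroblast markers passed in RKO minus HCT116 (0.229, 0.0384) and p53-linked noncoding RNAs in RKO minus SW48 (-0.203, 0.0384).

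Outside the named genes, 14 probe sets with no gene name here rose at least 2-fold in all 3 lines, against 0 that fell as far; 45 of the 22740 were called higher in all 3 lines and 1 lower.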

How the results depend on the processing

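No named gene and no gene list turned its direction past a threshold under any alternative, but the more frequent direction of calls changed in SW48 and RKO. With an intensity trend and a robust prior the counts of called genes rose to 1228 in HCT116, 870 in SW48, 760 in RKO, 215 shared and 288 that differ between lines. With each line fitted alone, on 4 arrays, they were 208, 115, 31 and 24 shared. An adjusted p under 0.01 gave 274, 188, 84, 639 for the mean effect, 42 shared and 12 that differ, and a 2-fold minimum gave 35, 29, 23, 20, 14 and 19, and 2120 between untreated lines. The filter on dim genes gave 438 in RKO, from fewer genes tested, and testing all probe sets gave 13836 between untreated lines, from more tested. Leaving out 1 array gave 260 to 692 genes in HCT116, 188 to 394 in SW48, 97 to 226 in RKO, 1028 to 1246 for the mean, 50 to 72 shared, 15 to 39 that differ, 7576 to 8199 between untreated lines and 32 to 36 of the 72 list tests; a group left with 1 array was assumed to vary like the others, and each such fit has fewer degrees of freedom. The 2 noncoding genes up at least 2-fold in all lines numbered 2 under each setting.

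The replicate numbers showed no pairing of the samples across all genes. The difference between replicates 1 and 2 correlated between untreated and treated arrays at 0.055 in HCT116, -0.039 in SW48 and -0.055 in RKO. These values cannot settle how the samples were paired when they were made. With the replicate number as a block the counts were 357, 218, 87, 960 for the mean, 44 shared and 1 that differs, and of the 12 named differences between lines 1 kept its call and 11 did not. Of the differences of lists between lines, 2 lost and 2 gained the call with this block. No block could be fitted for the untreated lines compared. Of the list tests, 5 lost the call with an estimated correlation (29 of 72 passed), and single omissions of an array ended it for integrated stress genes in SW48 (adjusted p = 0.0727 without untreated replicate 1 and 0.0574 without Nutlin-3a replicate 2), mismatch repair in SW48 (0.0528 without Nutlin-3a replicate 2) and RKO (0.208 without untreated replicate 1), cell cycle arrest in RKO (0.114 without untreated replicate 2) and the genes named with the study in RKO (0.0501 without Nutlin-3a replicate 2). Centring moved the median log2 fold change of all genes by 0.030 in HCT116, -0.030 in SW48 and -0.025 in RKO. Signal near background understates fold changes of dim genes.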

Other observations

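The test of zinc finger genes was chosen after the shared genes had been seen; the splits of arrays within lines were not.

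Of the genes in this paragraph, E2F2, PMAIP1 and DRAM1 come from the naming rule, and the others were named after their values were seen. The 77 genes that rose in all 3 lines include the apoptosis genes BAK1 and PMAIP1, the atypical E2F repressor gene E2F7, the lysosomal gene DRAM1, the nuclear lamin gene LMNA and the transcription factor gene STAT3. The 24 shared falls, of which 3 to 13 were left without any 1 array and 0 with each line fitted alone, include the lamin gene LMNB1, the replication genes MCM3 and EXO1 and the activator and repressor genes E2F2 and E2F8; in RKO the call of E2F2 was lost without any 1 array (adjusted p up to 0.202). Loss of LMNB1 and gain of E2F7 are known features of p53 responses as background.

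In the mean effect over the lines, the real arrangement gave 1520 genes. Of 100 of the 108 splits of the 4 arrays within each line, 1 gave as many, the real one, and the highest of the others gave 271. The other splits mix or swap treated and untreated arrays of a line, so real effects lower their counts. The duplicates may be technical, so this comparison cannot judge chance differences between cultures. The 31 splits that kept no line's real division gave at most 0.

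Zinc finger symbols among the shared rises (ZBTB7B, ZNF219, ZNF337, ZNF440, ZNF561 and ZNF79) raised the hypothesis that such genes respond more often. Of 519 protein-coding genes with a symbol starting ZNF, ZBTB or ZFP, 6 rose in all lines (1.16%), against 66 of 11211 others (0.589%). The odds ratio was 1.97 (95% interval 0.696 to 4.56; two-sided Fisher's exact test p = 0.137), so the data leave open whether they differ.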
